A study of Mus musculus with 8 samples.

How the data were processed

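Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin. Per the labels' protocols, splenocytes were enriched with DX5 beads, natural killer (NK) cells were sorted as CD49b+ CD3e- cells, and 200000 cells from each mouse entered the assay. Each mouse was a biological replicate. There were 4 libraries of mice wild-type for HSF1 (WT) and 4 of mice whose HSF1 carries alanine in place of serines 303 and 307 (MUT), all at steady state. The replicate numbers (4, 5, 6 and 7 for WT, 26, 27, 28 and 29 for MUT) are those of the labels and pair no samples. The labels give no strain or litter, and these numbers form a separate block for each genotype. Any other difference between the WT and MUT mice, or in their handling, could not be told apart from the genotype.

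The deposited files were 8 peak lists, 1 per library and not pooled, with a position, a name and an unnamed positive score per peak. The score is the authors' own value per peak. It was used to rank and filter peaks within its own list. Its median and its step, the spacing of its most frequent values, were also compared between the genotypes. Per the submitters' processing notes the build was mm10 (GRCm38) and the tools included Trimmomatic, Bowtie2 2.3.4.1, DESeq2 and DiffBind 3.0.12, with no role or order given. The peak caller, its threshold, the read filters and any shift of reads for the transposase are not given in the sources used here. The lists hold no read counts, so the sequencing depth of each library is unknown. A peak missing from a list is therefore a peak that was not called, which is not the same as closed chromatin. No count model was run, and intervals for shares of regions cover counting error only.

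Peaks of all libraries that overlapped by at least 1 bp were merged into regions. A region with a peak in at least 2 libraries was a consensus region. A MUT-only region had a peak in 4 of 4 MUT and 0 of 4 WT libraries, and a WT-only region the reverse. Genes came from a RefSeq table of the same build (GRCm38.p6) with 21887 protein-coding genes. That table gives gene starts and ends without strand, exons or transcript starts. The planned promoter class was therefore replaced by a gene-end class, a peak within 1 kb of either end of a protein-coding gene. Other peaks were placed in gene bodies or between genes. Each peak was linked to the gene with the nearest end, up to 50 kb away. Links by distance do not show which gene a region acts on.

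Library values were compared by an exact two-sided permutation test of the difference of group means, which has 70 assignments and a smallest p of 0.0286. Numbers of group-only regions were set against all 35 splits of the 8 libraries into 4 and 4, and each region was tested by Fisher's exact test. Similarity of libraries was the Jaccard index of covered bases, tested one-sided over the same splits. For accessible length per gene, the lengths of the linked peaks were summed for genes with a peak in at least 2 libraries. The total linked length of each library over these genes was scaled to the median of the libraries. The scaled lengths were tested with limma 3.58.1 (moderated test with trend) on log2(bp + 200). A log2 value is on the log2(bp + 200) scale and understates the change of genes with little length. Lengths printed in bp are not scaled, so a small difference in bp can differ in sign from its log2 value. The 22 gene lists held 406 entries, of which 402 matched the table. They were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, and by the share of peaks linked to list genes. Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05. Python 3.11.15, scipy 1.17.1 and R 4.3.3 were used.

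The tests of the report, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Later, after values had been seen, 4 alternatives and several tests of technical causes were added, and alternatives for peak shares were kept only for the 2 lists with an unadjusted p under 0.05. The bounds for the tests of technical causes were set later, after a first look that showed the list sizes and the numbers of MUT-only and WT-only regions. The rule takes up to 12 genes per direction past the threshold with the largest change among those whose 4 libraries of one genotype all lie above all 4 of the other. It adds 10 MUT-only and 10 WT-only regions, gene ends first and then by mean score percentile, and list genes with a group-only region, at most 5 per list. It always takes Hsf1, Hspa1a, Hspa1b, Hspa8, Hsph1, Hsp90aa1, Dnajb1, Ifng, Gzmb, Prf1, Eomes, Tbx21, Ncr1 and Klrk1. Predicted genes were counted and not named. Klra8, Bach2, Pou2af1, Blk, Cd3d, Cd79b and any other gene outside this rule were named after their values were seen.

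The code was tested on simulated data. Of 14262 simulated genes, 14% of 100 planted changes of log2 0.3 and 68% of 100 planted changes of log2 0.6 were recovered, and 6 of 88 calls were false. Changes were planted only in genes with a peak in all 8 libraries. The simulation therefore does not show how calls behave at genes with peaks in one genotype only. In simulated peak lists all 150 planted MUT-only and 50 planted WT-only regions were recovered. In all 162 and 62 were found, the unplanted ones having arisen at random. Simulated peaks of one region always overlapped and those of different regions never met. The recovery was therefore fixed by construction, and does not show how merging behaves where real peaks adjoin or their borders shift. A test of covered length region by region was tried after the data had been seen. It was set aside because too many of its calls in simulated data were false, and none of its results are used. The planned motif shares were not analysed here, since they need a genome sequence.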

Results

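The data describe open chromatin in NK cells, the cytotoxic innate lymphocytes, sorted from the spleens of unchallenged mice. HSF1 is the transcription factor that drives heat shock gene expression. The comparison sets 4 mice with wild-type HSF1 against 4 mice whose HSF1 has alanine at residues 303 and 307, and asks how accessibility in resting NK cells differs between these genotypes. The WT lists held 45004, 46102, 45066 and 42695 peaks (replicates 4, 5, 6 and 7). The MUT lists held 44827, 49627, 46623 and 44333 peaks (replicates 26, 27, 28 and 29). No 2 lists were alike, and the most similar pair shared a Jaccard index of 0.826. Read depth is unknown for these files.

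The chaperone genes and the main NK effector genes had called peaks in both genotypes. Hsf1 itself (chromosome 15, 76477362 to 76501155) had 782 ± 68.6 bp of linked peaks in WT and 832 ± 111 bp in MUT (SD, n = 4 each; limma, adjusted p = 0.893). The inducible HSP70 gene Hspa1b had 2229 ± 122 bp in WT and 1813 ± 265 bp in MUT (limma, adjusted p = 0.327), and its neighbour Hspa1a 819 ± 23.2 and 724 ± 81.0 bp (limma, adjusted p = 0.444). The natural cytotoxicity receptor gene Ncr1 had 2855 ± 198 and 3448 ± 377 bp (limma, adjusted p = 0.279). The log2 differences of the other always-named genes were 0.09 for Hspa8, -0.073 for Hsph1, -0.074 for Hsp90aa1 and 0.042 for Dnajb1 among the chaperones. They were -0.052 for Gzmb, 0.019 for Prf1, -0.10 for Eomes and -0.049 for Klrk1, and -0.038 for Ifng and -0.0067 for Tbx21, both of which turned positive without scaling. None of these 14 genes passed the limma test, with Eomes lowest among the rest at an adjusted p of 0.378. Each of the 14 had a gene-end peak in 8 of 8 libraries.

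Regions with called peaks in one genotype only were more numerous in MUT. Among 50044 consensus regions, 34461 (68.9%) had a peak in all 8 libraries, 292 were MUT-only and 89 were WT-only. The MUT-only region with the highest mean score percentile within its own lists (99.4), singled out after its values were seen, lay in the body of Stpg2 on chromosome 3 at 139564113 to 139564689, over 50 kb from a gene end. Most group-only regions were weak: their median score percentile was 23.5 (MUT-only) and 23.4 (WT-only), against 43.8 for all consensus regions and 19.4 for those not in all 8 libraries. At gene ends lay 22 of the MUT-only regions (7.53%) and 11 of the WT-only regions (12.4%), against 26.5% of all consensus regions and 13.1% of the 15583 that were not in all 8 libraries.

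At gene ends, the 10 named MUT-only regions were near Olfml3 (chromosome 3, 103738324 to 103738622), Oprd1 (chromosome 4, 132145052 to 132145403), Tmem141 (chromosome 2, 25620415 to 25620801), Nnmt (chromosome 9, 48538140 to 48538854), Glrx2, Ddr1, Mycl, Shisa4, Atf6b and Rpl29. Oprd1 encodes the delta opioid receptor, Nnmt nicotinamide N-methyltransferase, Ddr1 a collagen receptor and Atf6b a transcription factor of the unfolded protein response. The 10 named WT-only regions were near Klrc2 (chromosome 6, 129661293 to 129661802), Mc1r (chromosome 8, 123406894 to 123407134), Zfp574 (chromosome 7, 25082588 to 25082855), Prune2, Sdc4, Cdk2ap1, Gpr65, Pik3cd, Toe1 and Ndst1. Klrc2 encodes the activating receptor NKG2C and Pik3cd a catalytic subunit of phosphoinositide kinase in leukocytes. The Klrc2 region stood at the 36.1 percentile of the scores and the Ndst1 region at 0.544, the top and the bottom of the WT-only set named here.

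List genes gave further MUT-only regions. The kinase gene Jak1 had a pair in its body (chromosome 4, 101225916 to 101226509 and 101227105 to 101227574). The interleukin-2 receptor gene Il2ra (chromosome 2, 11672212 to 11672434) and the TGF-beta receptor gene Tgfbr1 had 1 each, so 4 of the 184 consensus regions of cytokine receptors and JAK-STAT signalling were MUT-only (Fisher's exact test, adjusted p = 0.510). Single MUT-only regions were linked to Usp18, an interferon-stimulated gene, to Ly6e and Emb of the immature NK cell list, and to Bag3, a co-chaperone of HSP70 and the 1 such region among 47 of the chaperone list. WT-only regions were linked to Spib of the B cell list and Lef1 of the T cell list. Cd244a, which encodes the receptor 2B4, had a MUT-only region (chromosome 1, 171562530 to 171562746) and a WT-only region (171551384 to 171551741). Several of these regions were near the bottom of their lists. The mean score percentile was 5.90 at Bag3, 7.72 at Emb, 4.04 at Tgfbr1, and 2.68 (MUT-only) and 6.37 (WT-only) at Cd244a. The other regions of this paragraph stood between 19.3 (Ly6e) and 62.5 (Jak1).

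**Figure D1:**
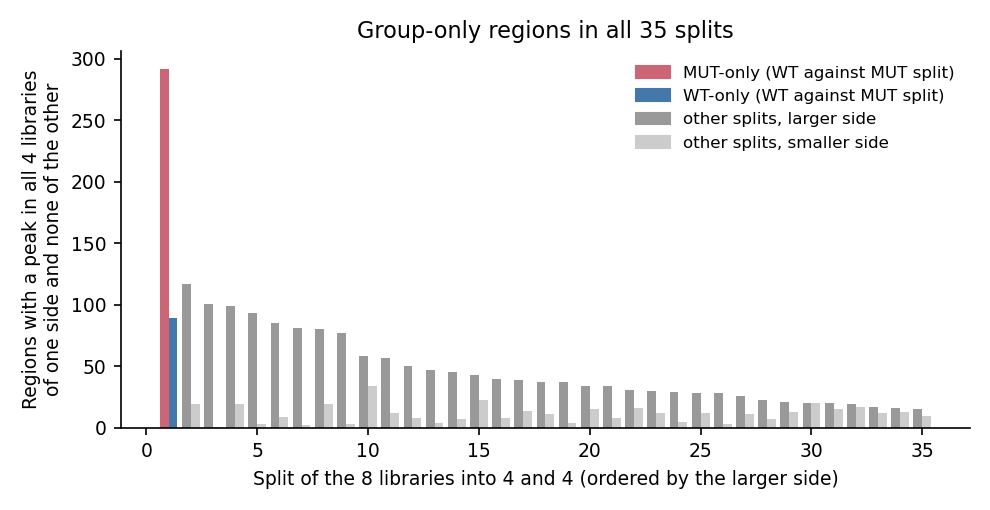
Number of regions with a peak in all 4 libraries of one side and in none of the other (vertical axis), for each of the 35 splits of the 8 libraries (horizontal axis), with a pair of bars per split for its larger and smaller side. The WT against MUT split gives 292 MUT-only and 89 WT-only regions, and the larger side of any other split reaches at most 117.

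No single region passed an adjustment. The smallest Fisher p that 4 against 4 allows is 0.0286; 381 regions reached it and 0 passed after adjustment. The balance of the sets and their members depended on the threshold: with the strongest 42695 peaks of each list there were 208 MUT-only and 138 WT-only regions, of which 199 and 72 were among those above, and with the upper 50% of each list there were 218 and 64, of which 13 and 1 were.

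Both WT-only and MUT-only regions were found at the NK receptor genes of chromosome 6. Between 128753904 and 130286658, a span set by the outermost WT-only regions, 6 of 131 consensus regions were WT-only. A group of 3 MUT-only regions, near Klrb1a, Klrc3 and a predicted gene, lay between 128620801 and 129641030 among 104 consensus regions and overlaps that span. The genes nearest to the WT-only regions were Klrc2, Klrb1c, which encodes the NK1.1 antigen, and Klra6, Klra7, Klra9 and Klra10 of the Ly49 receptor family (Klra6, Klra10, Klrb1a and Klrc3 were chosen after their values were seen). Accessible length fell at Klrc2 from 739 ± 127 to 50 ± 100 bp (log2 -1.99, SE 0.234, limma adjusted p = 0.0149) and at Klrb1c from 6347 ± 259 to 5360 ± 213 bp (log2 -0.27, SE 0.0407, limma adjusted p = 0.0321; SD, n = 4). It was 2181 ± 140 and 1161 ± 274 bp at the inhibitory receptor gene Klra9 (limma adjusted p = 0.0502). Klra9 passed with a pseudocount of 1000 bp (0.0472), without scaling (0.0411), with the gene of the merged region (0.0397), on autosomes only (0.0480) and without MUT replicate 29 (0.000959). It missed the threshold with equal numbers of peaks (0.106), at 10 kb (0.641), without the filter (0.0503) and with any of the other 7 libraries left out. Accessible length was 1586 ± 186 and 1135 ± 121 bp at the activating receptor gene Klra8 (limma adjusted p = 0.155).

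In the list of NK activating receptors and adaptors, 3 of 116 consensus regions were WT-only, linked to Klrc2, Klrb1c and Cd244a (Fisher's exact test, adjusted p = 0.0262). That test counts regions as independent, while the regions of Klrc2 and Klrb1c belong to the group of 6 above, so its p does not count as a call for the list. The share of peaks linked to this list was 0.232 ± 0.00259% in WT and 0.216 ± 0.00867% in MUT (exact permutation p = 0.0286, adjusted p = 0.314, n = 4). The difference turned to 0.0062 percentage points with the upper 50% of each list. Its unadjusted exact permutation p was 0.143 at 10 kb and 0.0571 without WT replicate 4, 5 or 6. With the upper 50% of each list Klrb1c stood at log2 0.55 and Klra9 at 0.12, neither past the threshold, and at 10 kb Klrb1c was at -0.19 (limma adjusted p = 0.422). Klrc2 missed the threshold without WT replicate 4 (limma adjusted p = 0.0538) and without WT replicate 5 (0.0577); Klrb1c missed it with any library left out but MUT replicate 26 and without scaling (0.0744).

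**Figure D2:**
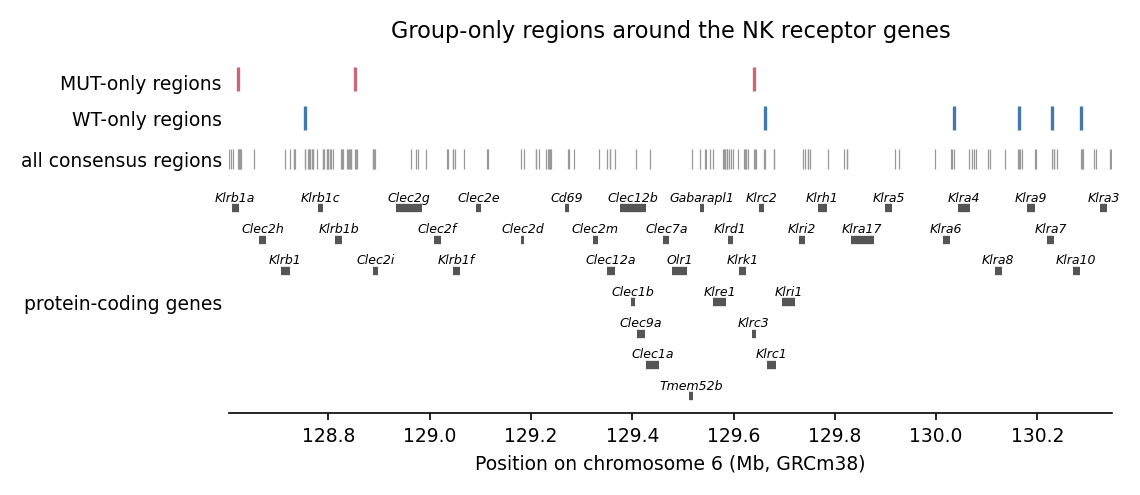
Map of the NK receptor genes on chromosome 6, from 128603904 to 130346658 (GRCm38), with protein-coding genes (predicted genes left out), all 153 consensus regions, and the WT-only and MUT-only regions as ticks along the position in Mb. The map holds 6 WT-only and 3 MUT-only regions.

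Among the genes past the threshold, more gained than lost accessible length in MUT, while the median log2 difference over all tested genes was -0.019. Cyp2j9 and Cyp2j6, neighbouring cytochrome P450 genes, had 828 ± 421 and 693 ± 250 bp of linked peaks in MUT and were listed at 0 in all 4 WT libraries (limma adjusted p = 0.0158 and 0.00661; SD, n = 4). Lpl and Mttp, which encode lipoprotein lipase and the microsomal triglyceride transfer protein, had 398 ± 37.5 and 407 ± 93.9 bp in MUT and were likewise listed at 0 in WT (limma adjusted p = 0.00620 and 0.00701). For genes listed at 0 in one genotype, here and below, the SD of that genotype is 0. Their limma p-values then rest largely on peaks called in 4 of 4 against 0 of 4 libraries. For that pattern Fisher's exact test gives an unadjusted p of 0.0286. At Cd48, which encodes the ligand of CD244, length fell from 1749 ± 86.3 to 1159 ± 184 bp (log2 -0.56, SE 0.0730, limma adjusted p = 0.0212). With 1 library left out, Cyp2j6, Lpl and Mttp passed in 8 of 8 fits. At 10 kb Cyp2j6 and Lpl had no value, and the only MUT-only region linked to Lpl lies 47022 bp from it. Cyp2j9 missed the threshold without WT replicate 4 (0.0518), WT replicate 5 (0.0549) or MUT replicate 26 (0.0677). Cd48 missed it without WT replicates 4, 5 or 7 (0.0742, 0.0549 and 0.0542) or MUT replicates 26 or 28 (0.0691 and 0.0617). With the upper 50% of each list Cyp2j9 and Cd48 missed it (0.419 and 0.768), and without scaling Cd48 (0.0631).

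Other genes listed at 0 in WT were Lefty1, a Nodal antagonist, with 665 ± 349 bp in MUT, Nnmt with 606 ± 285 bp, Lexm with 549 ± 180 bp, the lysosomal beta-galactosidase gene Glb1 with 441 ± 237 bp and the olfactory receptor gene Olfr1510 with 370 ± 12.3 bp. The vomeronasal receptor gene Vmn2r97 rose from 345 ± 120 to 1339 ± 222 bp (log2 1.48, SE 0.163). Among the genes that fell, Tmem178b (352 ± 137 bp in WT) and Zfp574 (237 ± 23.1 bp, all from its WT-only region, which itself did not pass) were listed at 0 in MUT. Others had log2 differences of -1.32 (SE 0.0963) for Ankrd36, -1.16 (SE 0.157) for Ddn, -0.76 (SE 0.121) for the transferrin receptor gene Tfr2, -0.76 (SE 0.119) for the Mediator gene Med21, -0.68 (SE 0.111) for the bone morphogenetic protein receptor gene Bmpr1a, -0.58 (SE 0.0754) for Greb1 and -0.56 (SE 0.0941) for Nfu1. All genes in this paragraph passed the limma test over 14262 genes, but most did not hold with a library left out. Only Lexm, Olfr1510, Vmn2r97 and Ankrd36 passed in 8 of 8 such fits, and with the upper 50% of each list Olfr1510 and Ankrd36 missed the threshold (adjusted p = 0.432 and 0.439) and Lexm had no value. Nnmt passed in 4 (highest adjusted p = 0.0549), Greb1 in 3 (0.0848), Ddn in 2 (0.0822), and Lefty1, Glb1, Med21, Bmpr1a and Nfu1 in 1 each (0.0989, 0.126, 0.100, 0.123 and 0.124). Tmem178b, Zfp574 and Tfr2 passed in 0 (0.135, 0.166 and 0.116). Bmpr1a and Nfu1 also missed the threshold in 4 of 8 other settings, Glb1 in 3 of 6, Greb1 in 2 of 8, Lefty1 and Tfr2 in 2 of 7, Zfp574 in 1 of 7, Tmem178b in 1 of 6 and Med21 in 1 of 8. At 10 kb Olfr1510, Glb1 and Tmem178b had no value.

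In all, 87 genes passed, 60 higher and 27 lower in MUT, and 1601 had an unadjusted p under 0.05. The balance was 67 to 54 with equal numbers of peaks, 24 to 21 without MUT replicate 27 and 63 to 19 without scaling. The groups did not overlap in 966 genes (6.77%), where chance gives 2.86%. Of the genes the rule named, Fubp1 (1452 ± 16.7 bp in WT, listed at 0 in MUT), Snrnp200 (listed at 0 in WT, 664 ± 67.9 bp in MUT) and Amdhd1 (listed at 0 in WT, 761 ± 317 bp in MUT) owed their values to peaks whose midpoint lay nearer to a different gene in the other genotype. When each peak took the gene of its merged region, chosen after seeing the data, 82 of the 87 genes passed again, 57 higher and 25 lower, and these 3 were not among them. With the upper 50% of each list 106 genes passed, of which 19 were among the 87; at a linking distance of 10 kb 41 passed, of which 36 were. The count fell to 24 without WT replicate 4, 22 without WT replicate 5, 48 without WT replicate 7, 29 without MUT replicate 26, 45 without MUT replicate 27 and 35 without MUT replicate 28.

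**Figure D3:**
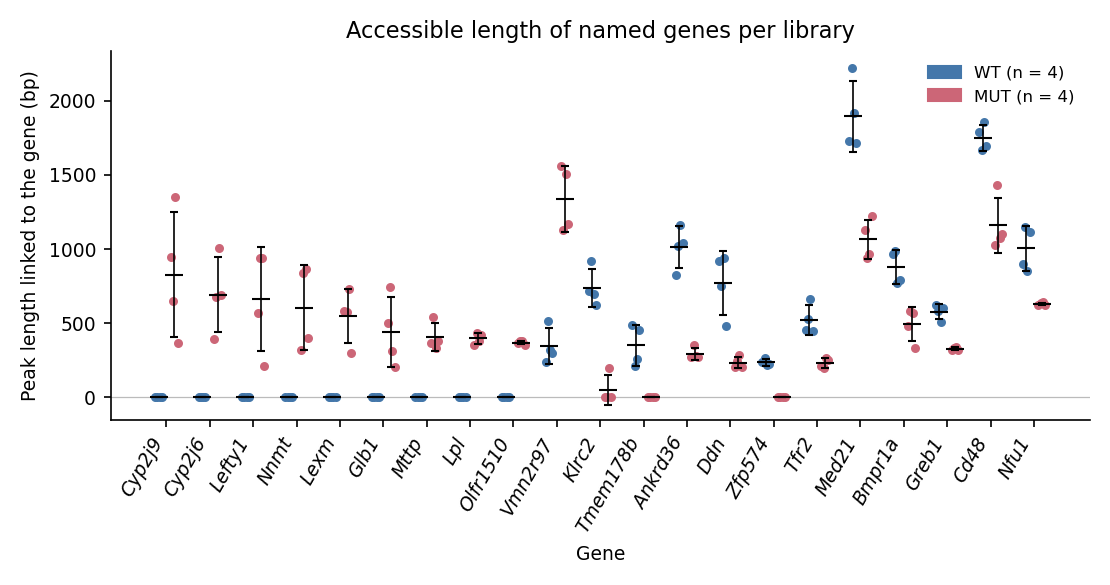
Length of linked peaks in bp (vertical axis) for the named genes past the threshold that also passed when peaks took the gene of their merged region, with 1 point per library, and the mean and SD in black, for WT and MUT (n = 4 each). Cyp2j9, Cyp2j6, Lpl and Mttp are at 0 in every WT library, while Klrc2 has 739 ± 127 bp in WT and 50 ± 100 bp in MUT.

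By camera and by fry, no fixed gene list passed as a whole for change in one direction. The HSF1-target chaperones had a median log2 difference of -0.035 over 22 tested genes (6 above 0), and the genes of the unfolded protein and integrated stress response -0.039 over 18; no member of either passed the limma test. NK activating receptors and adaptors had a median of -0.0077 over 20 genes with Klrc2 and Klrb1c lower, and 3 genes, Klra8 added, passed when adjusted over the list alone. NK inhibitory receptors and checkpoints had -0.067 over 20 genes, with Klra9 past the threshold when adjusted over the list alone. Immature NK cell genes had 0.11 over 15 genes, mature NK cell genes 0.0083 over 15, NK lineage transcription factors 0.00039 over 20 and cytotoxic effectors and cytokines -0.015 over 20. Bach2 of the lineage list (log2 -0.15, limma adjusted p = 0.0556) passed when adjusted over the list alone. Over all genes it passed only with a pseudocount of 1000 bp (limma adjusted p = 0.0474).

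Cytokine receptors and JAK-STAT signalling had a median of 0.030 over 27 genes, with Jak1 (6297 ± 528 bp in WT, 8226 ± 553 bp in MUT, limma adjusted p = 0.0670) past the threshold when adjusted over the list alone. Over all genes Jak1 passed only without WT replicate 7 (log2 0.40, limma adjusted p = 0.0058). The medians were 0.046 for homing and adhesion, -0.0057 for AP-1 and immediate early genes, -0.043 for NF-kB signalling, -0.027 for apoptosis and survival, -0.021 for interferon-stimulated genes, 0.0092 for glycolysis and mTOR and -0.041 for cell cycle. No member of these 7 lists passed, over all genes or over the list alone.

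Among markers of other cells, the B cell list had a median of 0.15 over 12 genes. Among the genes that passed when adjusted over the list alone, Pou2af1 (412 ± 119 bp in WT and 744 ± 124 bp in MUT) and Blk (399 ± 22.7 and 598 ± 128 bp) were higher in MUT and Spib (561 ± 53.8 and 348 ± 118 bp) lower; over all genes their limma adjusted p-values were 0.212, 0.225 and 0.181. The medians were -0.0049 for T cell markers, -0.057 for myeloid and dendritic cell markers, -0.0051 for basophil and mast cell markers, 0.069 for ILC1 markers and -0.052 for erythroid and platelet markers. The share of peaks linked to erythroid and platelet markers was 0.0408 ± 0.00157% in WT and 0.0345 ± 0.000807% in MUT (exact permutation p = 0.0286, adjusted p = 0.314; n = 4).

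By camera 0 of 22 lists passed with the preset or the estimated correlation (lowest adjusted p = 0.129 and adjusted p = 0.676), and 3 had an unadjusted p under 0.05 with the preset one: homing and adhesion, immature NK cell genes and NK inhibitory receptors. By fry 0 passed for change in one direction. The lowest adjusted p by fry was 0.0580, for NK inhibitory receptors and checkpoints, which were lower in MUT. By fry 7 lists passed for change in either direction, which does not set a list against other genes. Median and mean differed in sign for 5 lists, and median and camera for 3, the T cell, myeloid and basophil markers.

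Lists of one genotype were on average more alike than lists across genotypes. The mean Jaccard index was 0.804 for pairs of one genotype (0.774 to 0.826) and 0.787 for pairs across genotypes (0.771 to 0.796), so the ranges overlapped, with a difference of means of 0.0165 (exact one-sided permutation p = 0.0286, the smallest the 35 splits allow). Neither peak number nor covered length differed past the threshold: WT lists had 44717 ± 1439 peaks over 22.1 ± 0.507 Mb and MUT lists 46353 ± 2395 peaks over 22.9 ± 1.57 Mb (exact permutation p = 0.371 and 0.457, n = 4). The median peak width was 404 ± 5.12 bp in WT and 407 ± 5.91 bp in MUT. Gene ends took 29.0 ± 0.630% of WT peaks and 28.4 ± 0.943% of MUT peaks (exact permutation p = 0.429), gene bodies 41.4 ± 0.358% and 42.0 ± 0.435% (p = 0.114, exact), and 29.6 ± 0.423% and 29.6 ± 0.521% lay between genes (p = 0.886, exact). Over these library measures, with the median score and the score step in the same family, the lowest adjusted exact permutation p was 0.731. In the upper 50% of each list the gene-end share differed by -2.14 percentage points, MUT minus WT (exact permutation p = 0.0286, not adjusted).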

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

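Among the 88 groups of 4 libraries examined for a single library far from the others, 7 held one, where chance alone gives about 1 in 20 groups. WT replicate 7 had 0.283% of its peaks linked to mature NK cell genes, against 0.269 to 0.271% in the other WT libraries, and 0.0679% linked to ILC1 markers, against 0.0732 to 0.0737%. It also had 1888 bp of peaks at the perforin gene Prf1, against 2064 to 2096 bp. WT replicate 4 had 0.162% of its peaks linked to apoptosis and survival genes, against 0.171% in each of the others, and 2410 bp at Hspa1b, against 2151 to 2190 bp. MUT replicate 27 had 4007 bp at Ncr1, against 3188 to 3303 bp in the other MUT libraries. MUT replicate 29 had a median peak width of 398 bp, against 409 to 411 bp.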

How the results depend on the processing

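Of the alternatives, the gene of the merged region, autosomes only for accessible length, merging of peaks within 250 bp and leaving out chromosome 15 were chosen after seeing the data; the rest were planned. The motif alternatives were not run, since motif shares were not analysed here, and those for counts or normalized values do not apply to peak lists. No paired analysis was possible because the replicate numbers differ between the genotypes. The cause of the changes below was not tested unless stated. Similarity within genotypes stayed above that between genotypes, past its threshold, in all 4 other settings and with each library left out. The numbers of peaks and covered length stayed higher in MUT and short of the threshold throughout. The gene-end share differed by -2.14 percentage points in the upper 50% of each list, with an unadjusted exact permutation p of 0.0286. WT-only regions rose to 138 with equal numbers of peaks. They ranged from 102 without MUT replicate 26 to 198 without MUT replicate 27, and MUT-only regions from 346 to 522; a group of 3 meets the criterion more easily by construction. Genes past the threshold numbered 41 at 10 kb and 22 to 80 with 1 library left out, and lists 0 to 1, the 1 being immature NK cell genes without WT replicate 6. Some named genes gave no value in the upper 50%, at 10 kb or with the gene of the merged region. Of 140 values of named regions under the alternatives, 103 stayed in all 4 libraries of one genotype alone and 37 did not.

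With the upper 50% of each list, log2 differences were 0.27 for Eomes, 0.00045 for Greb1, 0.016 for Hsp90aa1, -0.16 for Hspa8, 0.088 for Hsph1, 0.084 for Ifng, 0.12 for Klra9, 0.55 for Klrb1c, 0.095 for Klrk1 and -0.0020 for Prf1. With equal numbers of peaks they were 0.0038 for Hsp90aa1 and 0.015 for Tbx21; at 10 kb 0.00064 for Greb1, 0.011 for Tbx21 and -0.019 for Il1b; without scaling 0.00057 for Ifng and 0.031 for Tbx21. With 1 library left out Hsf1 ranged from -0.0055 to 0.077, Klrk1 from -0.095 to 0.0058, Prf1 from -0.012 to 0.057 and Tbx21 from -0.051 to 0.031. None of these values passed the threshold. Of the other values of named genes, 39 under the alternatives and 138 with a library left out kept their sign but lost the call, and 5 and 2 gained one.

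List medians turned as well, among them the 2 largest, of B cell markers and immature NK cell genes. With the upper 50% they were -0.021 for B cell markers, 0.016 for NK activating receptors and adaptors, 0.079 for NK inhibitory receptors, 0.012 for T cell markers, 0.041 for apoptosis and survival, 0.066 for basophil and mast cell markers, 0.054 for erythroid and platelet markers, -0.0028 for glycolysis and mTOR and -0.0011 for immature NK cell genes. The difference in peak share was then 0.0062 percentage points for NK activating receptors and 0.00023 for erythroid and platelet markers. With equal numbers of peaks medians were -0.0088 for NK lineage transcription factors, 0.0068 for T cell markers, 0.022 for basophil and mast cell markers, -0.00054 for mature NK cell genes and 0.0049 for myeloid and dendritic cell markers. At 10 kb they were 0.013 for NF-kB signalling, 0.0057 for NK activating receptors, -0.012 for NK lineage transcription factors and 0.030 for basophil and mast cell markers. With 1 library left out, medians ranged from -0.0083 to 0.014 for NK lineage transcription factors, -0.011 to 0.010 for glycolysis and mTOR, -0.068 to 0.018 for myeloid and dendritic cell markers, -0.020 to 0.057 for basophil and mast cell markers, -0.035 to 0.00081 for cytotoxic effectors, -0.036 to 0.0088 for interferon-stimulated genes, -0.0060 to 0.016 for mature NK cell genes, -0.049 to 0.017 for NK activating receptors and -0.019 to 0.025 for T cell markers. No list passed in these settings apart from the 1 named above.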

Other observations

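Several immune genes outside the rule for named genes, chosen after their values were seen, were among the 87 that passed the limma test. Orai1, the store-operated calcium channel, had 1063 ± 97.0 bp of linked peaks in WT and 1822 ± 170 bp in MUT (log2 0.64, adjusted p = 0.0340). The cytokine gene Il1b had 386 ± 28.1 and 747 ± 168 bp (adjusted p = 0.0396), and the C-type lectin gene Clec4e 555 ± 44.4 and 799 ± 68.2 bp (adjusted p = 0.0391). Csf2rb, the shared receptor chain for GM-CSF, was listed at 0 in WT and had 256 ± 34.7 bp in MUT (adjusted p = 0.0355). The homeobox gene Hlx fell from 2666 ± 210 to 1956 ± 27.9 bp (log2 -0.44, adjusted p = 0.0233; SD, n = 4). These calls were weak: with the upper 50% of each list Il1b, Orai1 and Hlx missed the threshold, and Clec4e and Csf2rb gave no value. At 10 kb Il1b stood at -0.019 and Hlx missed it, as did Il1b and Clec4e without scaling (0.0846 and 0.0550), Il1b with a pseudocount of 1000 bp (0.0529) and Hlx with equal numbers of peaks (0.106). With 1 library left out, Csf2rb and Clec4e missed it for each of the 8, the highest adjusted p being 0.145 without MUT replicate 26 and 0.118 without MUT replicate 28. Il1b missed it for all but MUT replicate 29 (highest 0.119, without WT replicate 4), Orai1 for all but WT replicate 6 and MUT replicate 27 (highest 0.0970, without MUT replicate 26), and Hlx for all but WT replicate 6 and MUT replicate 29 (highest 0.0883, without WT replicate 4).

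Group-only regions were unevenly spread, which was seen in the data and not planned. Per 1000 consensus regions, MUT-only regions numbered 9.83 on chromosome 4, 8.86 on chromosome 6, 2.90 on chromosome 15, which holds Hsf1, and 0.975 on chromosome X. On chromosome 1, 4 MUT-only regions lay between 170950581 and 172015835, near Klhdc9, Cd244a, Vangl2 and a predicted gene, among 91 consensus regions. Cd244a encodes a receptor of the SLAM family. In the major histocompatibility complex, 4 MUT-only regions lay between 34136611 and 35705170 on chromosome 17, near H2-DMa, Atf6b, Mpig6b and Ddr1, among 151 consensus regions. A group of 4 near Clcn3 and Sh3rf1 on chromosome 8, 60937016 to 61306287, had 15 consensus regions in its span, the fewest of the 8 groups of 4.

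The tests of chance for region counts and lists, those of score steps, tandem families and neighbouring regions were chosen only after the results were seen, and the bounds of the others followed a first look at list sizes and numbers of group-only regions. For MUT-only regions, 1 of the 35 splits, the real one, gave as many (292, highest other 117). For accessible length per gene it was again 1 of 35 (87 genes, highest other 6). This argues against chance division of the 8 libraries for both, but 1 of 35 is the least that the splits allow. A difference between the WT and MUT mice other than HSF1 could give the same rank. For WT-only regions 5 of 35 splits gave as many on a side (89, highest other 117), so this count does not exclude chance. It sets the smaller side of the real split against the larger side of every split, and counts the real split through its 292 MUT-only regions. The smaller side of any other split held at most 34. For both sides together 1 of 35 splits, the real one, gave as many (381, highest other 136), which argues against chance for both sets together. With equal numbers of peaks, 1 of 35 splits, the real one, gave as many WT-only regions on a side (138, highest other 72). By the count of one side, only that setting argues against chance. In the other 6 alternatives 2 to 6 of 35 splits gave as many. For gene lists the real count was 0 (highest other 3), which 35 of 35 splits reach by construction, so that count says nothing.

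The surplus of MUT-only over WT-only regions stays open to technical causes. With equal numbers of peaks in every list the ratio fell from 3.28 to 1.51 (95% interval 1.21 to 1.88, which treats regions as independent), so list length may account for part of the surplus; the interval stays above 1 but does not clear the bound of 1.5 set for excluding it. The MUT-only regions stood at a median percentile of 23.5 in their lists, between the bounds of 10 and 25 set for regions at the detection limit, so that cause cannot be told apart from the genotype. Deeper sequencing in MUT, which would make the score steps smaller, met a mean step 0.0401 larger in MUT (exact permutation p = 0.257), and what the score measures is not given. For cells of other types, 0 of 292 MUT-only regions (up to 1.03%) were linked to the 73 marker genes, of which 0 are in another list, against 0.330% of consensus regions, so the count is too small to decide; the sort removed CD3e+ cells, and at Cd3d length was 1157 ± 9.74 bp in WT and 1145 ± 18.8 bp in MUT, at Cd79b 145 ± 180 and 366 ± 357 bp.

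The regions found in one genotype only, such as those at the NK receptor genes, were weighed against differences in DNA sequence between the mice. DNA of another strain carried along with the edited Hsf1 locus is argued against as the whole cause, since 4 of 381 regions (1.05%, 95% interval 0.287 to 2.67%) lay within 10 Mb of Hsf1. Tandem families were taken as at least 4 protein-coding genes of one name stem within 1 Mb. Reads shared within such families are argued against as the whole cause, with 3.67% of regions (2.02 to 6.09%) at these genes, among them Cyp2j6, Cyp2j9, Olfr1510 and Zfp574. Smaller families and predicted genes named Gm were not counted, which left out regions at Klrc2, Klrc3 and a group on chromosome 4, so the share may be too low. It was 6.74% for WT-only regions against 2.75% in a control set (Fisher's exact test, p = 0.0425). The control set held the 1966 consensus regions with a peak in exactly 4 libraries that were not all of one genotype. At the NK receptor genes of chromosome 6 the share was 83.3% of 6 WT-only regions (35.9 to 99.6%) against 59.2% of the 125 other regions there (Fisher's exact test, p = 0.402), so shared reads cannot be told apart from the genotype for these. A candidate explanation that stays open is that several chromosome segments differ between the WT and MUT mice. It was weighed against 10000 random sets drawn from the control set, which was not matched for score or position. Of MUT-only regions, 39.7% had another between 50 kb and 1 Mb away, against 22.6 to 36.0% in 95% of the random sets. Of WT-only regions, 24.7% did, against 2.25 to 20.2%. A MUT-only region lay within 1 Mb of 39.3% of WT-only regions (random sets 19.1 to 37.1%). Against this control set, these values go with that explanation. Regulation shared by neighbouring genes, including through HSF1, predicts grouping of this kind as well, so the substitution in HSF1 remains an untested biological explanation beside it.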
